A study of Mus musculus with 25 samples.

How the data were processed

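The study transplanted tumors of 4 mouse models of triple-negative breast cancer into the mammary gland of female mice, T11 and 2208L into Balb/c mice and PyMT-M and AT3 into C57BL/6 mice, and gave the randomized mice H3B-8800 or vehicle each day before collection. Per the labels, RNA came from whole tumors kept in RNAlater, and polyadenylated RNA was made into stranded libraries. The 25 libraries fall in 8 groups of model and treatment: 3 H3B-8800 and 3 vehicle libraries for T11, 4 and 4 for PyMT-M, 2 and 3 for AT3, and 3 and 3 for 2208L. The design text gives 3 or 4 tumors per condition, and AT3 with H3B-8800 has 2 here. The labels name no batch, and the replicate numbers do not say that samples of different treatments were paired.

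Per the submitters' processing notes, reads were aligned with HISAT2 2.0.4. The notes name the builds mm10 and hg38. The counting tool and the release of the gene annotation are not given in the sources used here. Each deposited file lists the same 163337 introns of 17596 genes, with 1 transcript per gene, on 21 chromosomes. For each intron the deposited columns hold the counts of reads inside the intron, the counts of reads overlapping it and the RPKM of the intronic reads. Recomputed from the deposited counts, the authors' RPKM matched to a relative error of at most 4.99e-12. The coordinates were those of mm10, since 99.9% of the introns match an intron of GENCODE M21. The 22 introns that span 10 bases or less lack values in some columns and were left out, which left 163315.

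The reads spliced across an intron were taken as the overlapping reads minus the intronic reads. Spliced reads of neighbouring introns of a gene correlated at 0.964 to 0.980 over the libraries, and intronic reads at 0.339 to 0.666. These correlations go with the reading, but cannot show whether reads across the edge of an exon and an intron were counted as spliced. Libraries held 10863779 to 22377777 overlapping reads, 9820825 to 19700955 spliced reads and 858362 to 5684308 intronic reads. A gene's count is the sum of the spliced reads over its introns, so genes without an intron and genes absent from the list were not measured, and a fragment that spans 2 junctions counts at both. Of all introns, 120544 hold no annotated exon. An intron that holds one can gain reads from another transcript, so its percent is not retention alone.

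The design was written for transcript TPM with limma, and named edgeR for counts. As the files held counts, edgeR was used. Groups, comparisons, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined, and the intron tests, DESeq2, the gene count as a median or upper quartile over introns, the fits without some libraries and the fits without T11 were chosen after. Genes with a CPM of at least 1 in at least 2 libraries were kept, 13001 in all. Counts were scaled by TMM and fitted in edgeR 4.0.16 (robust quasi-likelihood, 8 group means, all 25 libraries) under R 4.3.3, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The SE is the log2 fold change divided by the square root of the F value. Contrasts were H3B-8800 over vehicle in each model, the mean of the 4 contrasts, the mean of the responder models minus the mean of the nonresponder models, and vehicle tumors of PyMT-M over AT3 and of 2208L over T11.

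Introns were tested in the same way, with the log of the gene's spliced reads as offset, so that a change is relative to the spliced reads of the gene. The 52042 introns tested, in 9859 genes, lay in a kept gene and had a mean of at least 5 intronic and 10 spliced reads. The percent in an intron is its intronic reads over its intronic plus spliced reads. It was not adjusted for intron length, so it is not the percent of transcripts that keep the intron. The share of reads in introns was compared by exact permutation within each model, 2-sided, and over the 4 models by 100000 resamples within models. Of 32 gene lists, 31 had at least 5 members among the genes kept and were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, at a preset correlation of 0.01, with adjustment over the lists of a contrast. Camera with an estimated correlation, fry and a prior count of 0.2 were alternatives.

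Genes named for size were the 10 rising and 10 falling with the largest fitted change (5 and 5 for the responder and vehicle contrasts) among those with an adjusted p under 0.05, a mean CPM of at least 5 in the higher group and no overlap between the libraries of the groups compared. Predicted genes, pseudogenes and immunoglobulin and T cell receptor segments were not named. Up to 4 members of each passing list with the smallest p, and genes of splicing, interferon, proliferation and cell death chosen in advance, were named as well. Introns were named by a rule written after the files were seen: up to 10 of those that rose and up to 6 of those that fell in PyMT-M, AT3 and 2208L. Those that rose had no annotated exon and at least 20 reads in every library. A fold against a group with no reads takes 3 reads over the group as the floor. For genes with a mean CPM near that floor in a group, CPM are given without a fold.

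The other alternatives fixed in advance were no filter on low counts, a mean CPM of at least 5, median-ratio scaling, the libraries of the compared groups alone, library quality weights, the replicate number as a block, and leaving out each library in turn. Those foreseen for TPM, FPKM and isoforms had no values to run on, and the files hold no mitochondrial intron. For introns and genes DESeq2 1.42.0 was an added alternative, and for introns also limma on the log ratio, the library total as offset, introns without an annotated exon, and at least 20 intronic reads. Libraries with a mean log2(CPM + 1) of at least 4 for muscle markers or 2 for B cell markers were left out together in another. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1.

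The gene test was tested on simulated data with 200 genes changed by the drug in every model, at the depth of each library. The spread of a gene was that of the fit over all 25 libraries. Of genes changed 2-fold it recovered 25% in T11, 52% in PyMT-M, 23% in AT3 and 39% in 2208L, and of genes changed 4-fold 72%, 80%, 66% and 75%. The intron test, with 10000 changed introns, recovered 31.2%, 68.4%, 20.9% and 38.7% of those changed 4-fold in the same order, and with 200 changed introns, as for genes, 2%, 18%, 0% and 8%. In PyMT-M and 2208L as many genes or introns again were changed, so recoveries there are not like for like with T11 and AT3. Because the T11 libraries ran against their labels, they were kept as labelled, and results that rest on them were also computed without them.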

Results

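Tumors of 4 mouse models of triple-negative breast cancer, T11, PyMT-M, AT3 and 2208L, each begun from genetically engineered mice, had been transplanted into the mammary gland of female mice. The mice were then randomized to H3B-8800 or vehicle and treated. H3B-8800 is an oral small molecule that binds the SF3B complex, the part of the spliceosome that recognises the branch point of introns. Polyadenylated RNA of whole tumors was sequenced from 25 libraries in 8 groups. T11 had 3 H3B-8800 and 3 vehicle libraries, PyMT-M 4 and 4, AT3 2 and 3, and 2208L 3 and 3. The design text describes the replicates as separate tumors. The labels call PyMT-M and 2208L responders to H3B-8800 and T11 and AT3 nonresponders, without saying how response was measured.

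For each of 163337 introns of 17596 genes, every file gave the reads inside the intron and the reads overlapping it, and their difference was taken as the reads spliced across it. A library held between 9820825 and 19700955 spliced reads and between 858362 and 5684308 intronic reads. Gene levels are spliced reads scaled to library size (CPM), and retention is the percent of an intron's reads that lay inside it. A longer intron can hold more reads, so this is not the percent of transcripts that keep it. Both are given as mean ± SD over the n of the group above. Changes are log2 fold changes ± SE, with adjusted p-values from edgeR's quasi-likelihood test. Fixed lists of genes were tested with camera at a preset correlation between genes and again at an estimated one. In the order of the comparisons of genes below, 14, 8, 12, 13, 14, 10, 12 and 13 of 31 lists passed at the preset one, and not all are described. The SD holds counting error as well as the spread between tumors. Because the retention of the T11 libraries ran against their treatment labels, as described next, T11 libraries are called by their label throughout, and every T11 direction is that of the libraries labelled H3B-8800 over the libraries labelled vehicle.

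The first comparison asked whether H3B-8800 changed the removal of introns. In PyMT-M, AT3 and 2208L, intron reads rose broadly with the drug. Intron 11 of Amotl1, which encodes an angiomotin-like protein of cell junctions, went from 7.89% ± 4.08 to 94.0% ± 2.83 of reads inside it in PyMT-M, from 2.38% ± 4.12 to 81.3% ± 4.54 in AT3 and from 3.70% ± 1.60 to 77.7% ± 5.76 in 2208L. Its log2 changes relative to the spliced reads of the gene were 7.15 ± 0.58, 6.67 ± 0.79 and 6.47 ± 0.70 (adjusted p = 4.52e-11, 1.80e-06 and 7.46e-07). Intron 2 of Ripk1, a kinase of death receptor signalling, went from 0.833% ± 1.67 to 93.4% ± 2.48 in PyMT-M and from 1.85% ± 3.21 to 73.4% ± 11.9 in AT3. On the mm10 build the Amotl1 intron lies on chromosome 9, 14548807 to 14550391 and the Ripk1 intron on chromosome 13, 34009821 to 34010544, and neither holds an annotated exon.

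Retention rose in the same 3 models in intron 16 of the histone demethylase gene Kdm2a, from 23.2% ± 11.7 to 90.7% ± 2.27, from 13.7% ± 11.9 to 79.1% ± 9.07 and from 7.68% ± 6.65 to 67.0% ± 2.74 in PyMT-M, AT3 and 2208L. It rose in intron 4 of Phc2, a Polycomb gene, from 3.94% ± 1.94 to 76.8% ± 7.52, from 2.31% ± 1.21 to 61.2% ± 15.7 and from 1.34% ± 1.20 to 25.9% ± 5.50. It also rose in intron 2 of the transcriptional repressor gene Erf, intron 5 of the fatty acid desaturase gene Scd2, intron 4 of Phf12, intron 12 of the RNA helicase gene Ddx56 and intron 11 of Tm9sf3. The last went from 0.837% ± 0.320 to 47.1% ± 5.25 in PyMT-M, from 1.27% ± 1.15 to 22.5% ± 16.4 in AT3 and from 0.888% ± 0.187 to 20.3% ± 1.42 in 2208L.

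Of 52042 introns tested in 9859 genes, 31405 changed in PyMT-M (28449 higher in 7643 genes and 2956 lower), 10242 in AT3 (10076 higher and 166 lower) and 11197 in 2208L (10918 higher and 279 lower). PyMT-M and 2208L shared 10205 called introns, 10180 of them in the same direction, where 5984 were expected of independent lists. AT3 and 2208L shared 5644, with 5637 in the same direction against 2115 expected, and PyMT-M and AT3 shared 9554, with 9543 in the same direction against 5518 expected. A set of 5545 introns in 3252 genes rose in all 3 models, and 22 introns in 21 genes fell in all 3. The AT3 count was 1979 without H3B-8800 replicate 2, 4218 without vehicle replicate 1, 5298 without vehicle replicate 3 and 6462 with the AT3 libraries alone in the fit. The 2208L count was 5005 without vehicle replicate 1, a library with skeletal muscle transcripts, and 6916 without H3B-8800 replicate 1.

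The 22 introns that fell included introns of splicing factor genes and of other genes, such as intron 10 of Fbxl20. Intron 4 of Sf3b1, which encodes the largest protein of the SF3B complex (chromosome 1, 55014563 to 55016375, with an annotated exon inside), fell from 75.2% ± 9.32 to 13.8% ± 4.37 in PyMT-M, from 68.5% ± 8.57 to 36.5% ± 2.20 in AT3 and from 62.4% ± 10.2 to 25.1% ± 5.16 in 2208L. Its log2 changes were -3.71 ± 0.43, -2.01 ± 0.54 and -2.08 ± 0.46. Intron 1 of Rbm39, a splicing factor gene, fell from 74.5% ± 6.06 to 31.6% ± 6.77, from 73.8% ± 6.46 to 43.7% ± 3.71 and from 57.1% ± 11 to 17.8% ± 5.43. Intron 3 of Srrm1, intron 4 of Srsf5 and intron 3 of Rsrp1, all genes of serine and arginine rich proteins, fell in the same 3 models. Srsf2, Srsf5 and Srsf11 stood for 3 of the 21 genes, which was more than chance gives for a list of SR proteins and hnRNPs (Fisher's exact test, 2-sided, p = 1.64e-05, adjusted p = 0.000524 over 32 lists, a test chosen after the introns were seen). Only 4 of the 22, in Top2a, Pxk, Gmfg and Tmem80, held no annotated exon.

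**Figure D1:**
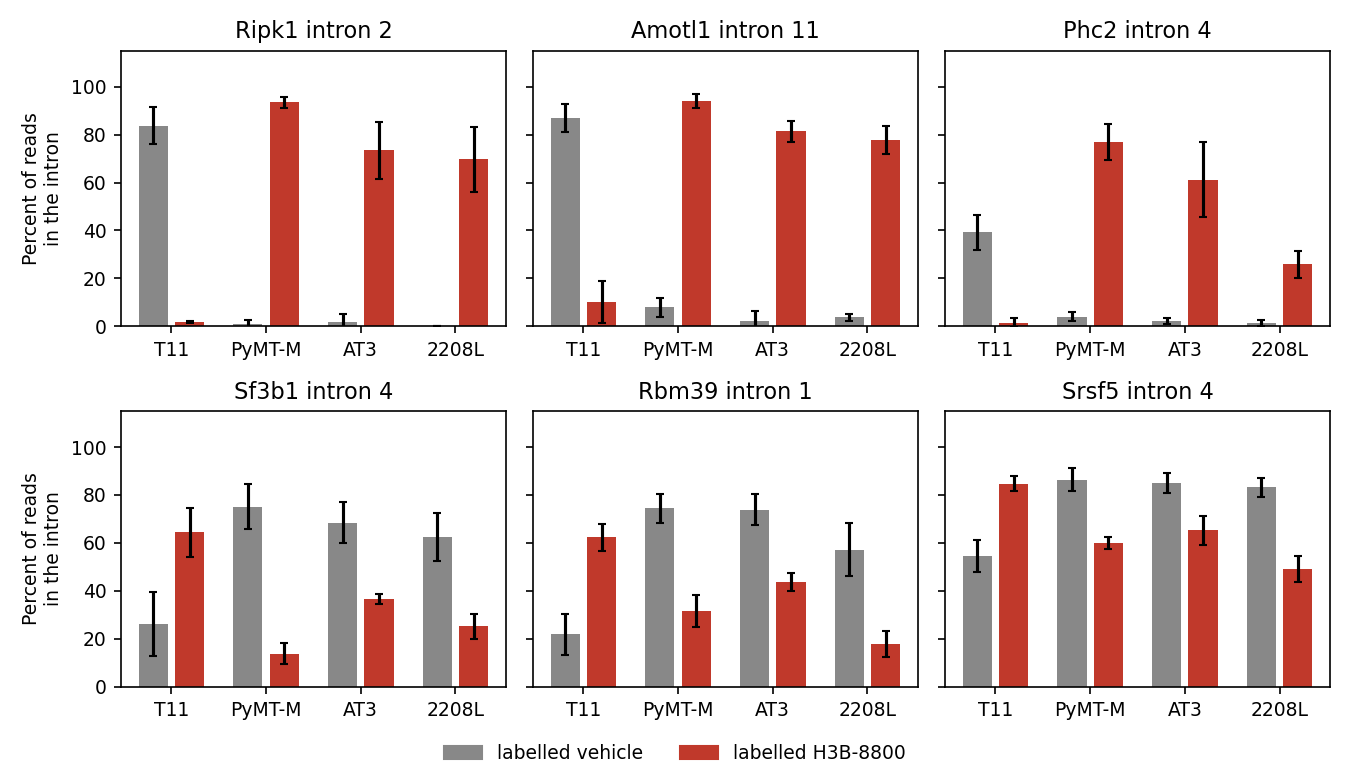
Percent of reads inside 6 introns (vertical axis), in the libraries labelled vehicle (grey) and labelled H3B-8800 (red) of each model (horizontal axis), as bars of the mean with the SD. Introns of Ripk1, Amotl1 and Phc2 were higher with H3B-8800 in PyMT-M, AT3 and 2208L and lower in the T11 libraries labelled H3B-8800, and those of Sf3b1, Rbm39 and Srsf5 ran the other way.

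In T11 the same introns moved in the opposite direction to the labels. Amotl1 intron 11 held 87.1% ± 5.77 of its reads in the libraries labelled vehicle and 9.998% ± 8.71 in those labelled H3B-8800, a log2 change of -5.61 ± 0.63. Ripk1 intron 2 stood at 83.8% ± 7.81 and 1.74% ± 0.330, and Sf3b1 intron 4 at 26.1% ± 13.3 and 64.4% ± 10.3. The libraries labelled H3B-8800 were lower in 10216 introns in 4629 genes and higher in 397. Of the 5545 introns that rose in the other models, 5517 (99.5%) were lower in the T11 libraries labelled H3B-8800, 4115 of them past the test and none higher past it. The 22 introns that fell in the other models were all higher there, 19 of them past the test. The T11 count of 10613 was 5703 without vehicle replicate 2, 6328 and 6343 without H3B-8800 replicates 1 and 2, and 3635 without vehicle replicate 3, H3B-8800 replicate 2 and 4 libraries of the other models, all of which held muscle or B cell transcripts.

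Pooled over the 5545 introns, 10.8% ± 2.64 of reads lay inside them in PyMT-M vehicle tumors and 49.99% ± 3.16 with H3B-8800. The values were 9.29% ± 3.35 and 29.7% ± 11.9 in AT3 and 6.65% ± 1.51 and 26.7% ± 2.21 in 2208L. In T11 they were 26.9% ± 10.4 in the libraries labelled vehicle and 8.54% ± 1.44 in those labelled H3B-8800. The 3 T11 libraries labelled vehicle, at 15.4% to 35.6%, lay above every vehicle library of the other models, which ran from 4.97% to 13.2%. The 3 labelled H3B-8800, at 7.24% to 10.1%, lay inside that range. The H3B-8800 libraries of the other models ran from 21.3% to 54.1%, so that T11 vehicle replicate 1, at 15.4%, lay between the ranges.

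**Figure D2:**
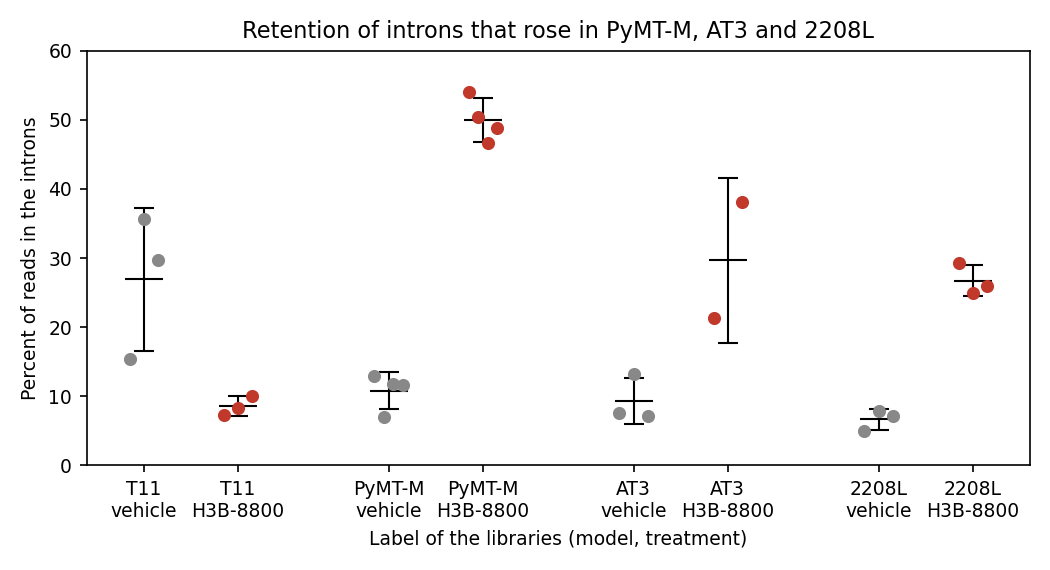
Percent of reads inside the 5545 introns that rose in PyMT-M, AT3 and 2208L (vertical axis) for each library (points), with the mean and SD of each labelled group (horizontal axis). The T11 libraries labelled vehicle sat between 15.4% and 35.6%, and those labelled H3B-8800 between 7.24% and 10.1%.

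Over all introns, intronic reads made up 23.7% ± 4.23 of reads with H3B-8800 and 14.3% ± 4.17 with vehicle in PyMT-M (exact permutation test, 2-sided, p = 0.0571, with 0.0286 the smallest p possible). In 2208L the values were 14% ± 0.826 and 9.47% ± 1.37 (exact p = 0.1, the smallest possible), in AT3 17.3% ± 4.37 and 11.9% ± 3.52 (exact p = 0.4, smallest 0.2). In T11 they were 10.5% ± 1.34 in the libraries labelled H3B-8800 and 14.4% ± 3.38 in those labelled vehicle (exact p = 0.2, smallest 0.1). The drug effect averaged over the 4 models was 3.87 points (permutation p = 0.0232 from 100000 resamples, 2-sided), and 6.46 points without T11 (permutation p = 0.0011). Averaged over the 4 models, 19711 introns changed (19222 of them higher), and 30582 did without the T11 libraries. The average was 12346 without AT3 H3B-8800 replicate 2. Shares added later gave PyMT-M its smallest exact p, 0.0286: introns without an annotated exon (18.4% against 8.31%) and the mean per gene (37.3% against 22.5%). Elsewhere p was 0.1 or more, but on the second the smallest possible, as no groups overlapped (T11 reversed).

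Next, drug effects in the responders PyMT-M and 2208L were set against those in the nonresponders T11 and AT3. Responders had the higher effect on Amotl1 intron 11, by a log2 of 6.28 ± 0.98 (adjusted p = 1.15e-05). That on Ripk1 intron 2 was higher, but PyMT-M and AT3 vehicle libraries held few or no reads in it, so no size is given. For Sf3b1 intron 4 the difference was -3.21 ± 0.45 (adjusted p = 2.37e-06). AT3 lay near 2208L for Amotl1 (6.67 and 6.47) and Sf3b1 (-2.01 and -2.08), with PyMT-M at 7.15 and -3.71. The effect differed for 16342 introns, 15374 higher in the responders. The reversed T11 libraries enter each difference, and that of Amotl1 came from them. Without T11 edgeR called 0 introns (3738 at an unadjusted p under 0.05), DESeq2 25 and limma on the log ratio 45. Without muscle or B cell libraries the count was 5644.

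Gene levels were compared next, model by model. In T11, some genes of antigen presentation and interferon response were higher in the libraries labelled H3B-8800. Tap1, the peptide transporter of MHC class I loading, went from 6.36 ± 1.74 to 50.01 ± 6.87 CPM (log2 2.97 ± 0.28, adjusted p = 2.21e-06). Cd74, the MHC class II invariant chain, went from 32.4 ± 12.2 to 289.5 ± 166 CPM (log2 3.16 ± 0.50, adjusted p = 0.000574). Lower in those libraries were Srsf5, a splicing factor gene, from 442 ± 43.5 to 165 ± 9.95 CPM (log2 -1.42 ± 0.17), and Lifr, the leukemia inhibitory factor receptor, from 28.2 ± 14.8 to 6.23 ± 2.24 CPM (log2 -2.16 ± 0.38). In all, 1525 genes (866 higher and 659 lower) of 13001 changed.

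Among MHC class I genes 9 of 16 members were called higher, 0 lower and 7 not called (10 higher and 0 lower adjusted over the list alone), including the class I transactivator gene Nlrc5 (log2 3.14 ± 0.41), the immunoproteasome gene Psmb9 (2.27 ± 0.31) and H2-T23 (1.58 ± 0.25). The list passed (adjusted p = 4.11e-08, and adjusted p = 0.106 with an estimated correlation). MHC class II genes counted 9 of 11 higher, 0 lower and 2 not called (9 and 0 adjusted over the list alone), with H2-Eb1 at log2 3.71 ± 0.60, H2-Ab1 at 3.51 ± 0.57 and H2-DMb1 at 3.59 ± 0.61 (adjusted p = 4.16e-09, and adjusted p = 0.109 with an estimated correlation). Interferon-stimulated genes counted 14 of 34 higher, 0 lower and 20 not called (18 and 0 adjusted over the list alone, adjusted p = 9.69e-11, and adjusted p = 0.290 with an estimated correlation). Oas1a stood at log2 2.16 ± 0.42, Irf7 at 1.99 ± 0.39 and Ddx60 at 1.66 ± 0.39, while Isg15 (0.27 ± 0.39), Ifit1 (0.10 ± 0.64) and Cxcl10 (0.61 ± 0.42) did not pass. Genes of double-stranded RNA sensing counted 9 of 21 higher, 0 lower and 12 not called (11 and 0 adjusted over the list alone), with Dhx58 (2.02), Zbp1 (2.00) and Irf3 (1.16) among them (adjusted p = 3.12e-06, and adjusted p = 0.106 with an estimated correlation).

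Some genes of the splicing machinery were called lower in the T11 libraries labelled H3B-8800. SR proteins and hnRNPs counted 1 of 24 higher, 12 lower and 11 not called (2 and 13 adjusted over the list alone, adjusted p = 4.44e-07, and adjusted p = 0.156 with an estimated correlation). SF3B complex and U2 snRNP genes counted 2 of 19 higher, 7 lower and 10 not called (2 and 12 adjusted over the list alone, adjusted p = 0.000141, and adjusted p = 0.142 with an estimated correlation). Tra2a stood at log2 -0.75 ± 0.13, Sf3b3 at -0.74 ± 0.12 and Sf3a1 at -0.45 ± 0.09, while Ddx42 was higher at 0.79 ± 0.17. Sf3b1 fell from 733 ± 191 to 438 ± 52.2 CPM (adjusted p = 0.00695). Oxidative phosphorylation genes counted 0 of 18 higher, 2 lower and 16 not called (0 and 6 adjusted over the list alone), with Ndufa4 at -0.95 and Atp5b at -0.46 (adjusted p = 6.01e-06, and adjusted p = 0.399 with an estimated correlation). Trp53 was higher at log2 0.60 ± 0.16. Mcl1, the BCL2 family gene, went from 44.8 ± 3.39 to 40.03 ± 2.01 CPM, Mki67 from 35.6 ± 16.3 to 54.7 ± 4.55 and Cdkn1a from 4.46 ± 0.891 to 4.51 ± 1.99, and none of these 3 passed. Ribosomal protein genes (adjusted p = 2.20e-05, and adjusted p = 0.520 with an estimated correlation) counted 0 of 20 higher, 1 lower and 19 not called (0 and 8 adjusted over the list alone). Death receptor genes (adjusted p = 0.00484, and adjusted p = 0.106 with an estimated correlation) counted 7 of 16 higher, 1 lower and 8 not called (7 and 1 adjusted over the list alone). Both lost their call without vehicle replicate 1 (adjusted p = 0.189 and 0.0689).

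Some lymphocyte genes were called higher in the T11 libraries labelled H3B-8800, with the reads of T cell and B cell markers concentrated in H3B-8800 replicate 2. The T cell markers had a mean log2(CPM + 1) of 3.52 there, 1.22 and 1.44 in the other 2 libraries of the group and 0.728 to 1.07 in those labelled vehicle. The B cell markers stood at 3.88 in replicate 2 and at 0.171 to 0.337 in the other 5 T11 libraries. T cell markers counted 8 of 14 higher, 0 lower and 6 not called (11 and 1 adjusted over the list alone, adjusted p = 0.000110, and adjusted p = 0.399 with an estimated correlation). Cd3d went from 0.159 ± 0.160 to 5.21 ± 7.49 CPM and Cd4 from 0.162 ± 0.183 to 4.95 ± 5.84 CPM. Without replicate 2 the list passed at adjusted p = 0.0249 with 1 member called. B cell and plasma cell markers counted 8 of 12 higher, 0 lower and 4 not called (11 and 0 adjusted over the list alone, adjusted p = 0.00163, and adjusted p = 0.520 with an estimated correlation), with Cd79b from 0.0895 ± 0.0781 to 10.5 ± 17.1 CPM. They did not pass without replicate 2 (adjusted p = 0.461). Mzb1, a plasma cell gene, had no read in the libraries labelled vehicle and stood at 4.76 ± 8.14 CPM over the others, a spread that exceeds its mean. Cytotoxic genes counted 6 of 11 higher, 0 lower and 5 not called (8 and 0 adjusted over the list alone, adjusted p = 2.20e-05, and adjusted p = 0.106 with an estimated correlation), with Gzmb, granzyme B, at log2 2.22 ± 0.55. Gzmb stood at 4.32, 1.27 and 2.40 CPM in H3B-8800 replicates 1, 2 and 3, so its reads were not concentrated in replicate 2. Dendritic cell markers counted 3 of 10 higher, 0 lower and 7 not called (5 and 0 adjusted over the list alone, adjusted p = 0.00976, and adjusted p = 0.227 with an estimated correlation; without replicate 2 adjusted p = 0.101). MHC class II genes passed without replicate 2 at adjusted p = 1.76e-07, with 7 called, and interferon-stimulated genes at 1.46e-11, with 10 called.

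The T11 count of genes was 920, 804 and 936 without H3B-8800 replicates 1, 2 and 3, 352 without H3B-8800 replicate 2, vehicle replicate 3 and the other libraries with muscle or B cell transcripts, and 13 with the T11 libraries alone in the fit. Inflammatory cytokine and NF-kB genes (adjusted p = 0.0440, and adjusted p = 0.469 with an estimated correlation) counted 3 of 22 higher, 0 lower and 19 not called (4 and 0 adjusted over the list alone). They lost the call without any of vehicle replicates 1 and 3 and H3B-8800 replicates 1 and 2 (adjusted p up to 0.109).

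In PyMT-M, a responder model, some genes of the cell cycle fell with H3B-8800, and some interferon-stimulated, macrophage and p53 target genes rose, though none of these lists passed with an estimated correlation (adjusted p = 0.772). Mki67, a proliferation marker, fell from 44.0 ± 22.1 to 16.5 ± 8.28 CPM (log2 -1.41 ± 0.35, adjusted p = 0.00636). Mx1, an antiviral interferon-induced gene, rose from 3.54 ± 1.05 to 19.7 ± 9.89 CPM (log2 2.48 ± 0.55, adjusted p = 0.00251) and the complement gene C1qa from 28.1 ± 11.1 to 83.9 ± 13.4 CPM (log2 1.57 ± 0.34). Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, rose from 68.1 ± 27.6 to 129 ± 31.9 CPM (log2 0.92 ± 0.31, adjusted p = 0.0334). Mcl1 rose from 39.5 ± 4.36 to 59.8 ± 6.39 CPM (log2 0.60 ± 0.12, adjusted p = 0.000840) and Sf3b1 from 553 ± 89.6 to 778 ± 51.8 CPM. The drug changed 3224 genes (1328 higher and 1896 lower).

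Among cell cycle genes 0 of 21 members were called higher, 12 lower and 9 not called (0 higher and 12 lower adjusted over the list alone), with Ttk at log2 -1.85 ± 0.31, Cdc20 at -1.79 ± 0.35, Bub1b at -1.62 ± 0.27 and Top2a at -1.26 ± 0.27 (adjusted p = 3.58e-06, and adjusted p = 0.772 with an estimated correlation). Interferon-stimulated genes counted 19 of 34 higher, 1 lower and 14 not called (22 and 1 adjusted over the list alone), with Oas2 (2.15 ± 0.48), Mx2 (2.08 ± 0.39), Cxcl10 (2.05 ± 0.40) and Isg15 (from 17.2 ± 3.26 to 48.7 ± 26.7 CPM) called (adjusted p = 5.17e-06, and adjusted p = 0.772 with an estimated correlation). Macrophage and monocyte markers counted 11 of 16 higher, 0 lower and 5 not called (13 and 1 adjusted over the list alone), with C1qb at 1.49 ± 0.26, C1qc at 1.46 ± 0.32 and Ccr2, the receptor of recruited monocytes, at 4.01 ± 0.74 (adjusted p = 5.17e-06, and adjusted p = 0.772 with an estimated correlation). For p53 targets the counts were 6 of 19 higher, 0 lower and 13 not called (6 and 0 adjusted over the list alone), with Trp53inp1 (1.73), Sesn2 (1.29) and Zmat3 (1.24) higher (adjusted p = 0.00330, and adjusted p = 0.772 with an estimated correlation), while Trp53 itself fell (log2 -0.54 ± 0.14).

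Oxidative phosphorylation genes counted 8 of 18 higher, 0 lower and 10 not called (8 and 0 adjusted over the list alone, adjusted p = 1.43e-05, and adjusted p = 0.772 with an estimated correlation), among them Uqcrfs1 (0.87) and Sdha (0.57). MHC class II genes counted 4 of 11 higher, 0 lower and 7 not called (4 and 0 adjusted over the list alone, adjusted p = 0.0124, and adjusted p = 0.772 with an estimated correlation), with Cd74 at log2 1.24 ± 0.41 and H2-DMa at 1.10 ± 0.29. Gzmb rose (log2 1.42 ± 0.45), while Cd8a (0.19 ± 1.01), Irf7 (0.61 ± 0.33) and Cd274, which encodes PD-L1 (0.77 ± 0.42), did not pass. The largest rises by the naming rule included Bdh1, a ketone body enzyme (log2 3.04 ± 0.36), Pon3 (3.11), Selp, the endothelial P-selectin (3.14), the chitinase gene Chit1 (3.16), the lysozyme gene Lyz1 (3.23) and Spon2 (3.33). The largest falls were in Ankrd37, a hypoxia-induced gene (log2 -4.43 ± 0.82), Dqx1 (-3.16), Kng2 (-3.15), Smtnl2 (-3.15), Smr3a, Tnni3, Fhl3, Fam64a, Proser3 and Trim45.

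Adipocyte markers were higher in PyMT-M with H3B-8800, 4 of 11 higher, 0 lower and 7 not called (6 and 0 adjusted over the list alone, adjusted p = 0.0237, and adjusted p = 0.804 with an estimated correlation), with Lpl from 10.2 ± 3.08 to 61.1 ± 44.8 CPM. Their mean log2(CPM + 1) was 3.42 and 4.76 in H3B-8800 replicates 3 and 4, 1.62 and 1.60 in replicates 1 and 2, and 0.834 to 1.63 with vehicle. The call was lost without any of vehicle replicates 1 and 3 and H3B-8800 replicates 3 and 4 (adjusted p up to 0.175). Fibroblast and matrix genes (adjusted p = 0.0124, and adjusted p = 0.804 with an estimated correlation) counted 2 of 15 higher, 0 lower and 13 not called (2 and 0 adjusted over the list alone), with Dcn at log2 1.85 ± 0.60. They lost the call without vehicle replicate 3 or H3B-8800 replicate 4 (adjusted p up to 0.0739). H3B-8800 replicates 1 and 2 held muscle transcripts. Without the libraries with muscle or B cell transcripts 1748 genes changed, and 2 cell cycle genes were called lower. With library quality weights 5007 genes changed.

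In AT3, a nonresponder model, 5 of 34 interferon-stimulated genes were called lower with H3B-8800, and the list did not pass with an estimated correlation (adjusted p = 0.161). Irf7, a transcription factor that amplifies type I interferon, fell from 16.4 ± 4.92 to 2.53 ± 1.67 CPM (log2 -2.72 ± 0.52, adjusted p = 0.0318). Usp18, a brake on interferon signalling, fell from 15.8 ± 8.46 to 1.42 ± 0.0379 CPM (log2 -3.46 ± 0.71) and the ubiquitin-like modifier gene Isg15 from 10.8 ± 6.05 to 1.72 ± 0.296 CPM (log2 -2.65 ± 0.55). Luc7l3, a U1 snRNP-associated splicing gene, rose from 164 ± 10.2 to 328 ± 25.6 CPM (log2 1.00 ± 0.12, adjusted p = 0.000982). Sf3b3, a protein of the SF3B complex, rose from 550.0 ± 30.5 to 1014 ± 51.1 CPM (log2 0.88 ± 0.14, adjusted p = 0.00767). With 2 H3B-8800 libraries, 39 genes (16 higher and 23 lower) changed.

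Among interferon-stimulated genes 0 of 34 members were called higher, 5 lower and 29 not called (1 higher and 24 lower adjusted over the list alone, adjusted p = 1.84e-24, and adjusted p = 0.161 with an estimated correlation). Mx2 went from 3.22 ± 1.27 to 0.0579 ± 0.0819 CPM and Irf9 fell by a log2 of 1.56. Ifit1 stood at 1.21 ± 0.230 CPM with vehicle and had no read with H3B-8800, at least 7.64-fold lower counting 3 reads over the group as the floor, and did not pass. Nor did Cxcl10 (log2 -2.33 ± 0.54, adjusted p = 0.0696) or Gzmb (-2.24 ± 0.62). Genes of double-stranded RNA sensing counted 0 of 21 higher, 1 lower and 20 not called (0 and 4 adjusted over the list alone, adjusted p = 1.88e-06, and adjusted p = 0.161 with an estimated correlation), with Ifih1, the sensor MDA5, at log2 -1.98 ± 0.43. Other genes that fell were Rbm5, a splicing factor gene (log2 -1.22 ± 0.19), Rin1 (-1.76), Rgs19 (-1.51), the sodium proton exchanger gene Slc9a8 (-1.48) and Myo19 (-1.26). Fbxl18 (2.95), Acyp2 (1.74), Map3k15 (1.27), Rabggtb (1.19), the corepressor gene Sin3b (1.07), Nhlrc2, Adam15 and Wdr33 rose. Sf3b1 (log2 0.49 ± 0.18), Mcl1 (0.25 ± 0.15), Mki67 (0.04 ± 0.44), Trp53 (0.10 ± 0.18), Cdkn1a (0.30 ± 0.44) and Cd274 (-0.74 ± 0.52) did not pass.

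T cell markers were at a mean log2(CPM + 1) of 2.22 in AT3 vehicle replicate 2 and 0.416 to 0.981 in the other 4 AT3 libraries, and B cell markers at 2.55 and 0.173 to 0.302. The interferon-stimulated list passed without that library at adjusted p = 1.10e-25, with 2 members called. The T cell list was lower with H3B-8800 (adjusted p = 0.0290, and adjusted p = 0.842 with an estimated correlation; 0 of 14 higher, 0 lower and 14 not called (0 and 0 adjusted over the list alone)) and stood at adjusted p = 0.993 without it. Of the other lists that passed, oxidative phosphorylation genes (adjusted p = 2.08e-06, and adjusted p = 0.505 with an estimated correlation), ribosomal protein genes (adjusted p = 4.98e-05, and adjusted p = 0.823 with an estimated correlation) and SR proteins and hnRNPs (adjusted p = 0.00473, and adjusted p = 0.599 with an estimated correlation) were higher, with no member called over all genes. They did not pass without H3B-8800 replicate 1 (adjusted p = 0.646, 0.854 and 0.322). Luminal markers (adjusted p = 0.0187), SF3B and U2 genes (0.0236, 1 called) and BCL2 family genes (0.0413) passed as higher, and cytotoxic (0.00880), endothelial (0.0236) and death receptor genes (0.0119) as lower, none of them with an estimated correlation (adjusted p of 0.161 or more). The count of 39 genes was 8, 9 and 15 without vehicle replicates 1, 2 and 3, 7 and 464 without H3B-8800 replicates 1 and 2, and 273 with DESeq2. edgeR called 0 with the AT3 libraries alone in the fit (1021 at an unadjusted p under 0.05) and 0 without vehicle replicate 2 and the muscle-bearing libraries of the other models (991 unadjusted).

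In 2208L, the other responder model, some macrophage genes rose with H3B-8800 and 6 of 15 hypoxia and glycolysis genes fell, though neither list passed with an estimated correlation (adjusted p = 0.244 and 0.564). Apoe, an apolipoprotein gene of macrophages, rose from 545 ± 389 to 2934 ± 418 CPM (log2 2.43 ± 0.42, adjusted p = 0.00170) and C1qa from 48.5 ± 34.9 to 202 ± 23.6 CPM (log2 2.06 ± 0.40). Egln3, an oxygen-sensing prolyl hydroxylase gene, fell from 68.5 ± 29.5 to 12.9 ± 2.24 CPM (log2 -2.40 ± 0.32, adjusted p = 0.000305) and Bnip3, a mitophagy receptor gene, from 215 ± 159 to 34.2 ± 24.0 CPM (log2 -2.65 ± 0.63). Krt14, a basal keratin gene, rose from 8.52 ± 2.12 to 173 ± 76.1 CPM (log2 4.34 ± 0.79). The drug changed 1344 genes (607 higher and 737 lower). Sf3b1 rose from 484 ± 30.7 to 766 ± 62.0 CPM (adjusted p = 0.0156).

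Among macrophage and monocyte markers 11 of 16 members were called higher, 1 lower and 4 not called (14 higher and 1 lower adjusted over the list alone), with Mertk at log2 2.60 ± 0.49 and C1qb at 1.52 ± 0.30 (adjusted p = 5.87e-10, and adjusted p = 0.244 with an estimated correlation). Hypoxia and glycolysis genes counted 0 of 15 higher, 6 lower and 9 not called (0 and 7 adjusted over the list alone), with Ankrd37 (-3.49 ± 0.76), Pdk1 (-1.72 ± 0.39) and Aldoa (-1.33 ± 0.28) lower (adjusted p = 0.000130, and adjusted p = 0.564 with an estimated correlation). For p53 targets the counts were 4 of 19 higher, 0 lower and 15 not called (7 and 0 adjusted over the list alone), with Cdkn1a at 1.33 ± 0.41, Sesn2 at 1.18 ± 0.28 and Sesn1 at 0.88 ± 0.24 (adjusted p = 0.000438, and adjusted p = 0.283 with an estimated correlation). Inflammatory and NF-kB genes counted 5 of 22 higher, 0 lower and 17 not called (7 and 0 adjusted over the list alone), with Il1a (2.70 ± 0.68) and Icam1 (1.28 ± 0.34) higher (adjusted p = 0.000722, and adjusted p = 0.289 with an estimated correlation). Immune checkpoint genes counted 2 of 7 higher, 0 lower and 5 not called (4 and 0 adjusted over the list alone), with Havcr2 (1.80) and Entpd1 (1.58) higher (adjusted p = 0.00719, and adjusted p = 0.222 with an estimated correlation). MHC class II genes counted 3 of 11 higher, 0 lower and 8 not called (4 and 0 adjusted over the list alone, adjusted p = 0.0102, and adjusted p = 0.786 with an estimated correlation), with Ctss at 1.57 and Cd74 at 1.49.

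Cell cycle genes passed the list test as lower (adjusted p = 0.000582, and adjusted p = 0.797 with an estimated correlation), but only Aurkb, a mitotic kinase gene, was called (log2 -1.57 ± 0.38), 1 of 21, and Mki67 stood at -0.83 ± 0.40 (adjusted p = 0.187). BCL2 family genes passed as higher (adjusted p = 0.0104, and adjusted p = 0.244 with an estimated correlation) at 1 of 13 higher, 0 lower and 12 not called (7 and 0 adjusted over the list alone), with Bcl2a1b called and Mcl1 at log2 0.34 ± 0.13 (adjusted p = 0.0994). Isg15 (-0.02 ± 0.39), Irf7 (0.12 ± 0.38), Cxcl10 (0.53 ± 0.43) and Ifit1 (0.52 ± 0.69) did not pass. By the naming rule, Gpnmb (3.97), Adamdec1 (3.76), Tnip3 (3.86), the netrin gene Ntn1, the Wnt receptor partner gene Lgr6, Anxa8, Gabbr2 and Enpp2, which encodes autotaxin (3.24), rose, and Duox1 (-3.14), Smtnl2, Mgarp, Tmod4, Lmcd1, Cd177, Espn and the casein gene Csn1s1 (-2.63) fell.

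Vehicle replicate 1 of 2208L held skeletal muscle transcripts, with a mean log2(CPM + 1) of 8.28 for the muscle markers against 0.403 to 1.86 in the other 2208L libraries. The muscle list was lower with H3B-8800 (adjusted p = 0.00928, and adjusted p = 0.832 with an estimated correlation; 0 of 13 higher, 0 lower and 13 not called (0 and 11 adjusted over the list alone)), and did not pass without that library (adjusted p = 0.334). Ckm, the muscle creatine kinase gene, went from 112 ± 192 to 0.0323 ± 0.0560 CPM. Heat shock genes were lower (adjusted p = 0.00928, and adjusted p = 0.564 with an estimated correlation; 0 of 11 higher, 2 lower and 9 not called (0 and 4 adjusted over the list alone)), with Hspa8 at log2 -0.89 ± 0.19, and did not pass without it either (adjusted p = 0.160). 590 genes changed without vehicle replicate 1, and with the muscle-bearing and B cell-bearing libraries of every model left out 343 did, with 1 macrophage marker called higher and 5 hypoxia genes lower. The count was 394 without vehicle replicate 3, 416 and 577 without H3B-8800 replicates 1 and 3, 2396 with the 2208L libraries alone in the fit and 3610 with library quality weights.

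**Figure D3:**
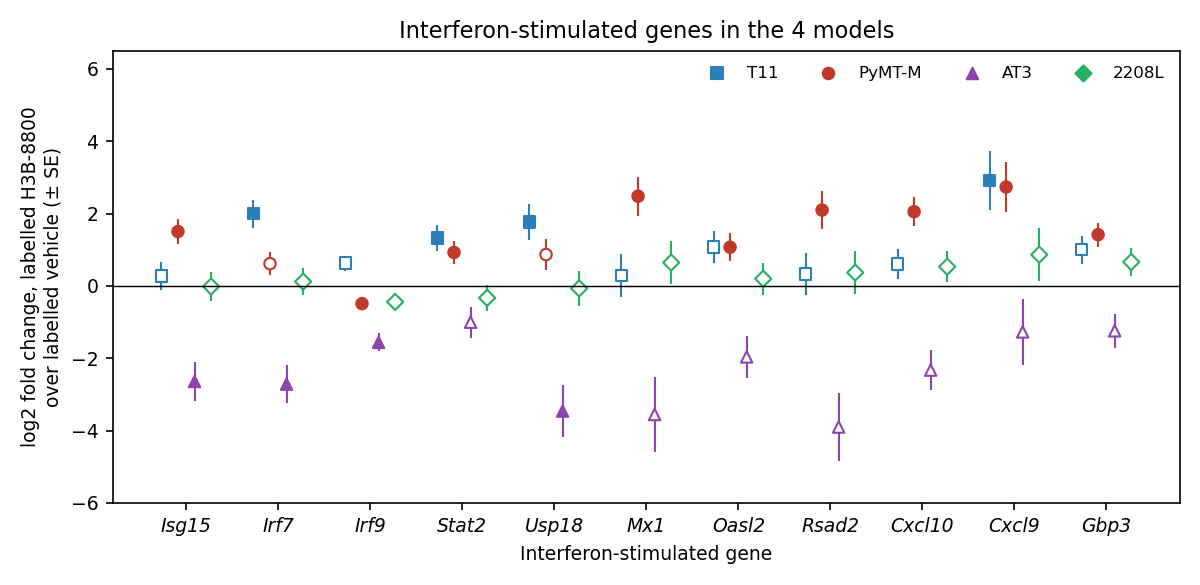
Log2 fold change ± SE of 11 interferon-stimulated genes (horizontal axis) for libraries labelled H3B-8800 over libraries labelled vehicle in each model, with filled symbols where the adjusted p was under 0.05. PyMT-M points lie above 0 and AT3 points below it for Isg15, Irf7 and Mx1.

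Averaged over the 4 models, with T11 entered by its labels, the complement gene C1qa rose by a log2 of 1.14 ± 0.19 (adjusted p = 0.00162) and the MHC class II genes H2-DMb1 by 1.65 ± 0.26 and Cd74 by 1.41 ± 0.23. Srfbp1, a cofactor of serum response factor, fell (log2 -0.83 ± 0.10, adjusted p = 0.000187), as did the DNA primase-polymerase gene Primpol (-0.36 ± 0.08), and these were the 2 genes that could be named by size of change. Macrophage and monocyte markers counted 12 of 16 higher, 1 lower and 3 not called (14 and 1 adjusted over the list alone), with Trem2 at 0.97 ± 0.17 (adjusted p = 7.72e-12, and adjusted p = 0.166 with an estimated correlation). MHC class I genes counted 7 of 16 higher, 0 lower and 9 not called (10 and 0 adjusted over the list alone, adjusted p = 2.93e-06, and adjusted p = 0.166 with an estimated correlation). MHC class II genes counted 7 of 11 higher, 0 lower and 4 not called (9 and 0 adjusted over the list alone, adjusted p = 2.89e-08, and adjusted p = 0.166 with an estimated correlation). Without the T11 libraries the class I list did not pass (adjusted p = 0.229, with 2 of 16 called), and the class II list stood at adjusted p = 0.0336 with 5 of 11 called, but at adjusted p = 0.810 with an estimated correlation. Tap1 rose on average (log2 0.56 ± 0.13) but stood at -0.24 without the T11 libraries. Cell cycle genes counted 0 of 21 higher, 3 lower and 18 not called (0 and 6 adjusted over the list alone, adjusted p = 2.93e-06, and adjusted p = 0.528 with an estimated correlation), and without T11 11 of 21 were lower (12 over the list alone, adjusted p = 7.59e-05, and adjusted p = 0.810 with an estimated correlation). Mcl1 rose by 0.26 ± 0.07 (adjusted p = 0.0196). In all 1089 genes (471 higher and 618 lower) changed, 3462 without the T11 libraries, 369 without the libraries with muscle or B cell transcripts and 1730 with DESeq2.

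The drug effect differed between responder and nonresponder models for 1724 genes (600 with the higher effect in the responder models and 1124 with the lower). Mx1 (log2 3.20 ± 0.72), Cxcl10 (2.15 ± 0.45) and Isg15 (1.93 ± 0.42) had the higher effect in the responder models, as had Apoe (1.79 ± 0.41), the p53 targets Sesn2 (1.25 ± 0.27) and Aen (1.05 ± 0.23), and Mak16, a ribosome assembly gene (0.86 ± 0.12). Ankrd37 (-3.97 ± 0.75), Egln3 (-2.36 ± 0.30), Aurkb (-1.86 ± 0.37) and Cdc20 (-1.45 ± 0.39) had the lower one. Interferon-stimulated genes counted 12 of 34 higher, 1 lower and 21 not called (19 and 1 adjusted over the list alone, adjusted p = 0.000129, and adjusted p = 0.684 with an estimated correlation). Macrophage markers counted 7 of 16 higher, 1 lower and 8 not called (12 and 1 adjusted over the list alone, adjusted p = 2.42e-05, and adjusted p = 0.684 with an estimated correlation). Cell cycle genes counted 0 of 21 higher, 7 lower and 14 not called (0 and 12 adjusted over the list alone, adjusted p = 4.25e-05, and adjusted p = 0.684 with an estimated correlation). Targets of p53 counted 6 of 19 higher, 0 lower and 13 not called (8 and 0 adjusted over the list alone, adjusted p = 0.000133, and adjusted p = 0.684 with an estimated correlation). In 2208L by itself neither Isg15 (log2 -0.019) nor Cxcl10 passed, and Isg15 fell in AT3. The T11 libraries enter by their labels. Without them the nonresponder side is AT3 alone, with 2 H3B-8800 libraries. Then 20 interferon-stimulated genes and 1 p53 target were called higher, and no macrophage marker or cell cycle gene was called over all genes. The lists then stood at adjusted p = 3.64e-30, 0.000576, 4.91e-06 and 0.00228, and at 0.121, 0.406, 0.406 and 0.577 with an estimated correlation. Without T11, 112 genes differed in all, while 2802 did without T11 vehicle replicate 1 alone, and 566 did without the libraries with muscle or B cell transcripts.

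Between models, PyMT-M and 2208L shared 658 called genes, 631 of them in the same direction, where 169 were expected of independent lists. AT3 and PyMT-M shared 25, with 23 in the same direction against 4.99 expected, and AT3 and 2208L 14, all in the same direction against 2.05 expected. T11, by its labels, shared 686 with PyMT-M, of which 624 went in opposite directions against 194 expected. It shared 327 with 2208L, 285 in opposite directions, and 28 with AT3, all in opposite directions.

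**Figure D4:**
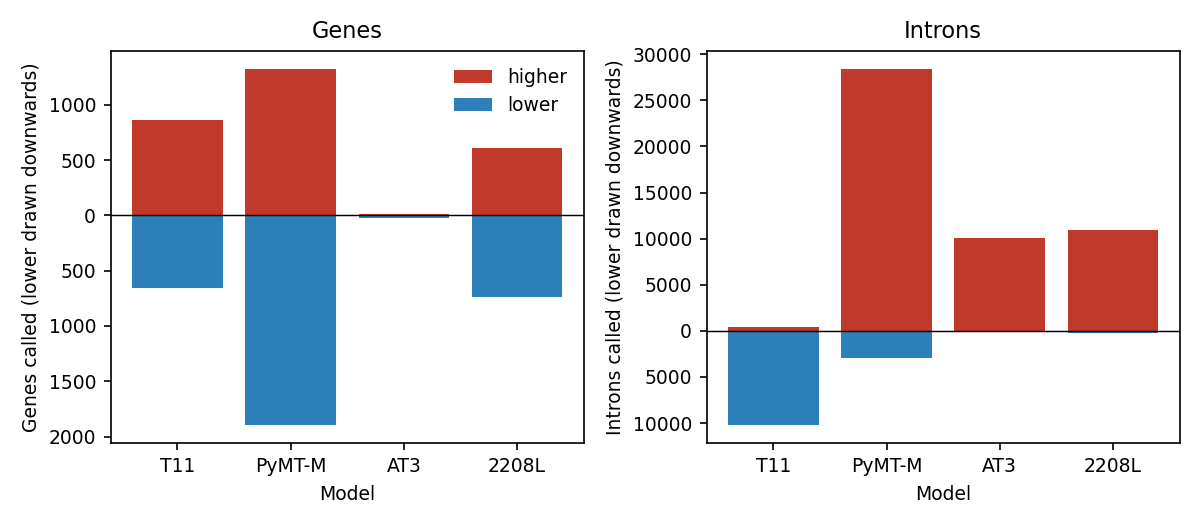
Genes (left) and introns (right) called at an adjusted p under 0.05 for libraries labelled H3B-8800 over libraries labelled vehicle in each model (horizontal axis), with higher ones drawn upwards and lower ones downwards on a count axis. In PyMT-M 28449 introns were higher, and in T11 10216 were lower.

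Vehicle tumors of a responder and a nonresponder model were compared within each host strain, to show how they differed without the drug. Many epithelial genes were higher in PyMT-M than in AT3 tumors. Cdh1, E-cadherin, stood at 329 ± 92.6 CPM in PyMT-M and 1.49 ± 0.244 in AT3 (log2 7.78 ± 0.38), and Prom1 at 359.7 ± 59.8 and 0.234 ± 0.143 (log2 10.56 ± 0.44). Vim, vimentin, was lower in PyMT-M, at 1068 ± 264 CPM against 4821 ± 1037 (log2 -2.17 ± 0.22), as was the neutrophil gene S100a9 (-6.63 ± 0.56). The chemokine gene Cxcl1 stood at 0.115 ± 0.0960 CPM against 50.3 ± 30.4. In all 7805 genes differed, 4168 higher in PyMT-M and 3637 lower.

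Luminal markers counted 11 of 13 higher, 2 lower and 0 not called (11 and 2 adjusted over the list alone, adjusted p = 2.88e-06, and adjusted p = 0.0798 with an estimated correlation), with Elf5, a luminal progenitor transcription factor gene, at 479 ± 49.1 CPM in PyMT-M and 0.0556 ± 0.0483 in AT3. Basal markers counted 11 of 13 higher, 0 lower and 2 not called (12 and 0 adjusted over the list alone, adjusted p = 0.000376, and adjusted p = 0.206 with an estimated correlation), with Itgb4 at log2 7.71 ± 0.51. For p53 targets the counts were 15 of 19 higher, 0 lower and 4 not called (15 and 0 adjusted over the list alone, adjusted p = 0.000473, and adjusted p = 0.206 with an estimated correlation), with Cdkn1a at 3.77 ± 0.40 and Btg2 at 3.86 ± 0.37. Mesenchymal genes counted 0 of 13 higher, 10 lower and 3 not called (0 and 10 adjusted over the list alone, adjusted p = 0.000772, and adjusted p = 0.206 with an estimated correlation). Cell cycle genes counted 0 of 21 higher, 17 lower and 4 not called (0 and 20 adjusted over the list alone, adjusted p = 2.88e-06, and adjusted p = 0.534 with an estimated correlation), with Mcm3 at -2.54 ± 0.23. Neutrophil markers counted 1 of 11 higher, 9 lower and 1 not called (1 and 10 adjusted over the list alone, adjusted p = 0.000728, and adjusted p = 0.206 with an estimated correlation). Ltf, lactoferrin, a neutrophil list member also made by mammary epithelium, ran against its list (log2 12.56 ± 0.92). Inflammatory genes counted 3 of 22 higher, 17 lower and 2 not called (3 and 17 adjusted over the list alone, adjusted p = 0.000315, and adjusted p = 0.206 with an estimated correlation). SF3B and U2 genes counted 1 of 19 higher, 14 lower and 4 not called (1 and 14 adjusted over the list alone, adjusted p = 0.00254, and adjusted p = 0.25 with an estimated correlation), with Sf3b3 at -1.35 ± 0.11. Macrophage markers counted 0 of 16 higher, 11 lower and 5 not called (1 and 12 adjusted over the list alone, adjusted p = 0.00697, and adjusted p = 0.616 with an estimated correlation). Col9a1 had no read in AT3 and was at least 21718-fold higher in PyMT-M, and Slc14a1 had none in PyMT-M and was at least 578-fold higher in AT3, each with 3 reads over the group as the floor.

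Many epithelial genes were likewise higher in 2208L vehicle tumors than in the T11 libraries labelled vehicle, whose labels the retention of introns ran against. Krt8, a luminal keratin gene, stood at 1144 ± 223 CPM in 2208L and 1.29 ± 0.542 in T11 (log2 9.75 ± 0.47), and Vim at 1114 ± 93.8 and 9097 ± 2770 (log2 -3.03 ± 0.25). Luminal markers counted 9 of 13 higher, 1 lower and 3 not called (9 and 1 adjusted over the list alone) and were the only list of any comparison to pass with both correlations (adjusted p = 4.10e-07, and adjusted p = 0.0373 with an estimated correlation), with Cdh1 at log2 9.52 ± 0.46 and Cldn7 at 9.96 ± 0.50. Tfap2c, a luminal transcription factor gene, had no read in the T11 libraries labelled vehicle and was at least 2738-fold higher in 2208L, with the same floor. Fibroblast genes counted 0 of 15 higher, 12 lower and 3 not called (0 and 12 adjusted over the list alone, adjusted p = 0.000276, and adjusted p = 0.444 with an estimated correlation), with Pdgfra at -3.82 ± 0.52. Mesenchymal genes counted 1 of 13 higher, 10 lower and 2 not called (1 and 11 adjusted over the list alone, adjusted p = 0.00178, and adjusted p = 0.348 with an estimated correlation). Zeb1 stood at -4.03 ± 0.47, while Cdh2, N-cadherin, was higher at 5.99 ± 0.63. MHC class I genes counted 12 of 16 higher, 0 lower and 4 not called (12 and 0 adjusted over the list alone, adjusted p = 0.00128, and adjusted p = 0.444 with an estimated correlation), with Tap1 at 2.41 ± 0.27. MHC class II genes counted 8 of 11 higher, 1 lower and 2 not called (8 and 1 adjusted over the list alone, adjusted p = 0.00206, and adjusted p = 0.444 with an estimated correlation), with H2-Ab1 at 4.78 ± 0.59. SR proteins and hnRNPs counted 0 of 24 higher, 16 lower and 8 not called (2 and 16 adjusted over the list alone, adjusted p = 0.000276, and adjusted p = 0.444 with an estimated correlation), with Srsf5 at -1.98 ± 0.17. In all 5929 genes differed, 3000 higher in 2208L and 2929 lower, and 3748 did with these 6 libraries alone in the fit. Interferon-stimulated genes passed as higher in 2208L (adjusted p = 0.0297, and adjusted p = 0.780 with an estimated correlation), at 14 of 34 higher, 2 lower and 18 not called (14 and 2 adjusted over the list alone), but not without T11 vehicle replicate 1 (adjusted p = 0.410).

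Because the T11 labels are in doubt, 2208L vehicle tumors were also set against the T11 libraries labelled H3B-8800, where 5034 genes differed. Luminal markers were again higher (adjusted p = 2.79e-08, and 0.0194 with an estimated correlation), with Krt8 at log2 10.17 ± 0.48, and Vim again lower at -2.56 ± 0.25. Fibroblast genes (adjusted p = 0.00147) and mesenchymal genes (0.00382) passed as lower, though not with an estimated correlation (0.954 and 0.476). The lists of MHC class I (adjusted p = 0.893, with 4 of 16 called higher), MHC class II (0.776, with 2 of 11 higher and 1 lower), interferon-stimulated genes (0.329) and SR proteins and hnRNPs (0.257, with 1 of 24 higher and 5 lower) did not pass. Tap1 stood at log2 -0.56 ± 0.25 (adjusted p = 0.0861), H2-Ab1 at 1.27 ± 0.50 (adjusted p = 0.0463) and Srsf5 at -0.56 ± 0.16 (adjusted p = 0.00892). The last 2 were still called in the same direction at a smaller size, and Tap1 was not called.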

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

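The tests of the T11 labels, of unspliced RNA or DNA, and of T cell and B cell genes without single libraries were chosen after the results they measure were seen. Among 19 measures in each of 2 groups of 4 libraries, 1 library lay apart from its group, where about 1.9 would by chance. This was PyMT-M vehicle replicate 3, whose T cell marker mean of 0.964 lay under the median of 1.05 of the others, with a gap to its nearest neighbour of 0.868 of the range of the group.

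Differences between models drew attention as well. The drug effect differed between responder and nonresponder models for 1724 genes and 16342 introns, T11 entering by its labels. The drug effect on interferon-stimulated genes differed between PyMT-M and AT3 (camera at the preset correlation, adjusted p of the list 2.60e-31). The effect was called higher in PyMT-M for 18 members and lower for 1. It differed between 2208L and AT3 as well (1.15e-17), with no member called over all genes. Adjusted over the list alone, the effect was higher in 2208L for 22 members and lower for 1. The drug effect on genes of double-stranded RNA sensing differed between PyMT-M and AT3 (0.000110, with 3 of 21 members called). It differed between 2208L and AT3 too (0.000154, with none called over all genes and 5 over the list alone). None of these passed with an estimated correlation: adjusted p was 0.227 and 0.387 for PyMT-M over AT3 and 0.2855 for both lists in 2208L over AT3. With fry the adjusted p was 0.00609 and 0.0524 for the PyMT-M effect minus the AT3 effect. It was 0.0327 for both lists for the 2208L effect minus the AT3 effect. AT3 has 2 H3B-8800 libraries, and these comparisons between models also compare host strains or tumors of different origin.

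The first pattern weighed is that introns retained in the H3B-8800 libraries of PyMT-M, AT3 and 2208L were retained in the T11 libraries labelled vehicle: 99.5% of the 5545 had a lower fitted retention in those labelled H3B-8800. More unspliced RNA or DNA in the libraries labelled vehicle is argued against, since the intronic reads of 1608 long introns that moved least in the other models changed by a median log2 of 0.032 in T11, against -2.29 for the 5545, and the introns that fell elsewhere ran the other way. An exchange of only some T11 libraries is argued against too: all 6 lay on the side of the other treatment, although vehicle replicate 1, at 15.4%, lay between the vehicle libraries (up to 13.2%) and the H3B-8800 libraries (from 21.3%) of the other models, and for the introns that fell it stood at 47.7%, with the H3B-8800 libraries at 38.0% to 61.8% and the vehicle libraries at 66.0% or more. Exchanged treatment labels in T11 may explain the pattern, and the values they need are there. A response of T11 that is opposite to the other models was not tested and stays open, and no library was moved between groups.

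The next pattern is that the spliced reads of 1896 genes in PyMT-M and 737 in 2208L fell with H3B-8800. If retained introns lowered the spliced reads of their own gene, a count taken at the upper quartile of a gene's introns should lose much of the change. It kept 98.8% of the median log2 change in PyMT-M and 98.1% in 2208L, and 84.1% and 66.4% of the genes were still called. Falls that come from a few retained introns of a gene are argued against. Where most introns of a gene were retained the check cannot tell, since the upper quartile then falls too, and 54.7% of tested introns rose in PyMT-M. A fall in transcription or in RNA stability was not tested.

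The last pattern is that lymphocyte and interferon genes differed where single libraries held lymphoid transcripts. Without T11 H3B-8800 replicate 2 the B cell list stood at adjusted p = 0.461, with 8 called members becoming 0 in edgeR (11 adjusted over the list alone before), so lymphoid tissue in that library may account for it. The T cell list stood at adjusted p = 0.0249, with 8 called members becoming 1, and interferon-stimulated genes at 1.46e-11, with 14 becoming 10, though with every library neither list passed at an estimated correlation (adjusted p = 0.399 and 0.290), so only the genes still called argue against that library as the whole source. In AT3 interferon-stimulated genes stood at 1.10e-25 without vehicle replicate 2, and their median log2 change went from -1.62 to -1.70, which argues against lymphoid cells in that library, though with every library the list stood at adjusted p = 0.161 with an estimated correlation. Whether drug or tumor site brought the lymphocytes was not tested.

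Other splits of the libraries were counted for each comparison of groups of 3 or more. By the rule set in advance, that under 0.05 of splits give as many, chance was argued against for the genes of PyMT-M (3224 called, 407 in the highest of the other splits), the average (1089 and 243) and PyMT-M over AT3 vehicle tumors (7805 and 4428). In each of these 1 split, the real one, gave as many. The same holds for the introns of PyMT-M (31405 and 0). The PyMT-M comparisons had 35 splits, so their share is the smallest possible, and the shares were not adjusted over the comparisons. For the responder difference the real split also stood alone (1724 and 1011 genes, 16342 and 8384 introns), but the splits exchanged treatment labels within models, so they tested the drug effects and not the grouping of models by response. Without T11 that difference held 112 genes and, in edgeR, 0 introns (3738 at an unadjusted p under 0.05, with 25 called by DESeq2 and 45 by limma). For the introns of the average 2 of 60 splits gave as many (19711, and 23160 in the other), and the other split exchanged every PyMT-M label while it kept most T11 labels. With 10 splits the share cannot fall under 0.05 for the genes of T11 (1525, highest other 11), of 2208L (1344 and 0) and of 2208L over T11 vehicle tumors (5929 and 224), or for the introns of T11 (10613 and 315) and 2208L (11197 and 0). AT3, with 2 libraries against 3, was not counted.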

How the results depend on the processing

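The alternatives with DESeq2, with gene counts taken as a median or upper quartile over introns, without some libraries together or without T11, with the T11 libraries labelled H3B-8800 in place of those labelled vehicle against 2208L, and all alternatives for introns and for the share of reads in introns were chosen after the data were seen. Of 10058 repeats of the 508 results for single genes, 8860 kept their direction and their side of the threshold, 937 lost the call, 215 gained one and 46 reversed. For the 95 results for single introns, 1278 of 1325 were kept, and 7 reversed. Counts of genes moved by over 1.5 times in 38 of 169 repeats and counts of introns in 27 of 125. Median-ratio scaling moved no count of genes by that much.

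For genes, without a filter the count was 24 for AT3. With a mean CPM of at least 5 the count was 68 for AT3. With the compared libraries alone the counts were 13 for T11, 0 for AT3, 2396 for 2208L and 3748 for 2208L over T11 vehicle tumors. With quality weights the counts were 5007 for PyMT-M, 2 for AT3 and 3610 for 2208L. With the replicate number as a block the counts were 949 for T11, 9 for AT3, 820 for 2208L and 523 for the average. With DESeq2 the counts were 273 for AT3 and 1730 for the average. With the median over introns the count was 9 for AT3. At the upper quartile of introns the count was 12 for AT3. Without the libraries with muscle or B cell transcripts the counts were 352 for T11, 1748 for PyMT-M, 0 for AT3, 343 for 2208L, 369 for the average and 566 for the responder difference. Without T11 the counts were 3462 for the average and 112 for the responder difference. Leaving out 1 library at a time gave 804 to 1683 for T11, 7 to 464 for AT3, 394 to 1455 for 2208L and 1298 to 2802 for the responder difference. In edgeR the AT3 count of 0 came with 1021 genes at an unadjusted p under 0.05 for the compared libraries alone and 991 without the libraries with muscle or B cell transcripts. Of 96 list tests that passed over the 8 contrasts, 1 passed with an estimated correlation. Fry tests a list without setting it against the other genes. It passed 12 of 31 lists in T11, 6 in PyMT-M, 3 in AT3 and 7 in 2208L. It passed 7 in the average, 1 in the responder difference, 20 in PyMT-M over AT3 and 19 in 2208L over T11. Fewer libraries leave fewer degrees of freedom, and otherwise the cause was not tested.

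For introns, with the compared libraries alone the count was 6462 for AT3. With the replicate number as a block the count was 3421 for AT3. Without the libraries with muscle or B cell transcripts the counts were 3635 for T11, 2728 for 2208L and 5644 for the responder difference. Without T11 the counts were 30582 for the average and 0 for the responder difference. Among introns without an annotated exon the counts were 6314 for T11, 18917 for PyMT-M, 6680 for AT3, 6730 for 2208L, 12221 for the average and 9502 for the responder difference. With at least 20 intronic reads the counts were 6810 for T11, 15366 for PyMT-M, 6753 for AT3, 11314 for the average and 9891 for the responder difference. Fewer introns are tested among those without an exon and those with at least 20 reads. Leaving out 1 library at a time gave 5703 to 12555 for T11, 1979 to 11982 for AT3, 5005 to 9244 for 2208L and 12346 to 22013 for the average. Without T11, the responder difference had 3738 introns at an unadjusted p under 0.05 in edgeR, and DESeq2 called 25. The share of reads in introns as a mean per gene differed by -7.42 points in T11 by its labels, 14.8 in PyMT-M, 10.4 in AT3 and 7.66 in 2208L.

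Of the results that reversed, Tap1 on average and Irf7, Psmb9 and Tap1 in 2208L over T11 vehicle tumors had been called. Cdkn1a in T11 went from -0.018 to 0.022 (no filter), 0.0297 (stricter filter), 0.036 (compared libraries alone), 0.015 (upper quartile) and 0.20 (without muscle or B cell libraries). Ifit1 in T11 went from 0.10 to -0.24 (quality weights). Cd8a in PyMT-M went from 0.19 to -0.29 (quality weights) and -0.0297 (replicate block). Cd8a in AT3 went from -1.28 to 2.68 (without muscle or B cell libraries). Mki67 in AT3 went from 0.038 to -0.0011 (no filter), -0.018 (stricter filter), -0.0097 (compared libraries alone), -0.033 (quality weights), -0.036 (replicate block), -0.68 (median over introns) and -0.40 (upper quartile). Trp53 in AT3 went from 0.10 to -0.031 (without muscle or B cell libraries). Irf7 in 2208L went from 0.12 to -0.061 (median over introns). Isg15 in 2208L went from -0.019 to 0.017 (stricter filter) and 0.16 (without muscle or B cell libraries). Tap1 in the average went from 0.56 to -0.24 (without T11). Cidea in the responder difference went from 4.30 to -1.36 (without muscle or B cell libraries). Irf7 in 2208L over T11 vehicle tumors went from 1.76 to -0.23 (other T11 libraries). Psmb9 in 2208L over T11 vehicle tumors went from 2.09 to -0.18 (other T11 libraries). Tap1 in 2208L over T11 vehicle tumors went from 2.41 to -0.56 (other T11 libraries). Mcl1 intron 2 in AT3 went from -0.23 to 0.021 (library total as offset). Mcl1 intron 2 in 2208L went from 0.26 to -0.017 (without muscle or B cell libraries). With 1 library left out, the ranges were Cdkn1a in T11 -0.41 to 0.25, Ifit1 in T11 -0.40 to 0.72, Isg15 in T11 -0.056 to 0.50, Cd8a in PyMT-M -0.16 to 0.60, Bax in AT3 -0.034 to 1.06, Cd8a in AT3 -4.02 to 2.71, Cox5a in AT3 -0.046 to 1.27, Krt7 in AT3 -0.10 to 4.89, Mki67 in AT3 -0.42 to 0.38, Rps14 in AT3 -0.0077 to 1.09, Trp53 in AT3 -0.031 to 0.13, Irf7 in 2208L -0.0040 to 0.25, Isg15 in 2208L -0.11 to 0.16, Mcl1 intron 2 in T11 -0.27 to 0.10 and Mcl1 intron 2 in 2208L -0.017 to 0.55. The cause was not tested. Where a group keeps 1 library, it is taken to vary like the other groups. The alternatives foreseen for TPM, FPKM, mitochondrial genes and isoforms were not run, since the files hold no such values. At the depth of these libraries, 20.9% of introns changed 4-fold were recovered in AT3 and 68.4% in PyMT-M on simulated data with 10000 changed introns, and 0% and 18% with 200. As many introns again were changed in PyMT-M, so its recovery is not like for like with that in AT3.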

Other observations

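The values for lists of introns were chosen after the data were seen, and the test of the interferon difference was not. Of 149 introns of SF3B and U2 genes, 97 rose and 6 fell in PyMT-M, 32 and 3 in AT3, and 31 and 3 in 2208L. Of 155 introns of SR protein and hnRNP genes, 78 rose and 14 fell in PyMT-M, 24 and 6 in AT3, and 20 and 12 in 2208L. Over all introns 54.7% rose and 5.68% fell in PyMT-M, and differences between lists were not tested. Cell cycle genes had 78 of 109 higher and 2 lower in PyMT-M, and genes of double-stranded RNA sensing 86 of 125 higher and 2 lower. Intron 1 of Mcl1, which encodes the BCL2 family protein whose splicing sets its function, went from 7.92% ± 3.97 to 20.6% ± 5.28 in PyMT-M (log2 1.68 ± 0.46, adjusted p = 0.00204) and from 7.07% ± 4.04 to 16.9% ± 1.53 in 2208L (log2 1.59 ± 0.53, adjusted p = 0.0271). In AT3 it went from 9.12% ± 3.42 to 23.4% ± 3.35 (adjusted p = 0.0770) and did not pass. Of the 22 introns that fell in PyMT-M, AT3 and 2208L, 18 hold an annotated exon, so reads of an included exon enter their percent.

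Of 34 interferon-stimulated genes, 19 were called higher and 1 lower with H3B-8800 in PyMT-M and 5 lower in AT3, and neither list passed with an estimated correlation (adjusted p = 0.772 and 0.161). A candidate explanation is that the drug acts on interferon genes differently in the 2 models. The difference passed at a preset correlation (adjusted p = 2.60e-31) and with fry (adjusted p = 0.00609). It stood at adjusted p = 0.227 with an estimated correlation, so the tests differ and leave it open.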
